A study of Mus musculus and Homo sapiens with 36 samples.

How the data were processed

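The 36 samples were placed in 16 groups from their titles. They covered smartSHAPE in HEK293T cells (16 samples, with 1, 5, 25 or 125 ng of RNA and NAI-N3 or DMSO for 5 min), smartSHAPE in Ly6Chi and Ly6Clo mouse colonic macrophages (4 samples), RNA-seq of Reg1 KO and WT iBMDMs at 0 or 3 h of LPS at 100 ng/ml (12 samples) and uvCLAP of Reg1 or GFP in Raw264.7 cells (4 samples). The groups, the fixed gene lists, the tests, the rule for named genes and most alternatives were chosen before the data were examined. Nothing in the labels says that replicates were separate cultures or animals, so p-values measure the spread between these samples, which may be technical. Intervals and floors given with counts cover counting error only.

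The submitters' processing notes name the tools cutadapt, Trimmomatic, Bowtie2, STAR and DESeq2 and the builds hg38 and mm10, without versions, role or order. Versions, settings and the read counter are not given in the sources used here. Per the labels' protocols, smartSHAPE libraries came from Trizol-isolated, rRNA-depleted RNA, with random-primed reverse transcription, RNase I digestion and capture on streptavidin beads, and the RNA-seq libraries came from a KAPA RNA Hyper Prep kit.

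The deposited smartSHAPE files hold 1 row per transcript with a reactivity score from 0 to 1 for each nucleotide, or no score. Both NAI-N3 samples of a group name the same file, so each group is a single pooled profile. How the authors used the DMSO samples, pooled replicates and scaled the score is not given in the sources used here, and the DMSO samples enter no comparison of their own. Scores from 0 to 1 that the authors scaled within a file can shift between files, which limits comparisons of mean reactivity. A further deposited score at 5, 25 and 125 ng, of unstated unit, was read as transcript abundance and used to rank transcripts only. Its correlation between inputs, on a log2 scale with 1 added, was 0.973 for 5 and 25 ng, 0.946 for 5 and 125 ng and 0.938 for 25 and 125 ng.

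The deposited RNA-seq tables hold whole-number counts per Ensembl gene for 6 libraries at 0 h and 6 at 3 h, and the authors left genes without a count in a table out of it. The tables held 22721 and 22581 genes, 20878 in both. They were joined over 24424 genes, with a count of 0 where a gene was in 1 table only (1843 and 1703 genes). Of the 14225 genes tested, 12 were in 1 table only. Every row named a gene, and symbols were found for all but 83 identifiers. Strand use in counting is not given in the sources used here, so counts of overlapping or antisense genes are uncertain, and MHC and other multigene families can share reads.

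The deposited peak list gives, per its name, Piranha peaks with a bin size of 50. Its signal column holds the authors' reads per bin, and its p-value column, also the authors', stays under 0.01. A further deposited score, 0.01 in 11945 peaks, was not used. Whether replicates or the Reg1 and GFP libraries were pooled is not given in the sources used here. Read and p values were used to describe and rank peaks within the list only.

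Counts were normalised with TMM factors and filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), and all 12 libraries were fitted in 1 model with a mean per group. Genes were tested with glmQLFit (robust) and glmQLFTest, with Benjamini-Hochberg adjustment over 14225 genes and a threshold of 0.05. Levels are CPM with these factors, as mean ± SD. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its exact 95% interval. One count was worth from 0.0719 to 0.143 CPM, which sets the precision of low values.

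The 27 fixed lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01, where at least 5 members were measured. That left 20 lists, adjusted together. camera was run again with a correlation estimated from the data, and fry was run beside it. Of 667 list genes, 601 were found in the tables. The lists covered Regnase-1 target mRNAs, inflammatory cytokines and chemokines, NF-kappaB components and feedback, interferon-stimulated genes, mRNA decay and RNA-binding regulators, and iron handling. They covered MHC class II and antigen presentation, glycolysis and hypoxia response, cholesterol biosynthesis, cholesterol efflux and LXR targets, cell cycle, alternative activation, macrophage identity and lysosome. They also covered the unfolded protein and integrated stress response, NRF2 targets, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, and monocyte-like and resident colonic macrophage markers. Markers of fibroblasts, epithelial cells, T and NK cells, B and plasma cells, neutrophils, dendritic cells, and mast cells and eosinophils made up the rest.

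Named genes were Zc3h12a, the 8 largest rises and 8 largest falls past the threshold with a mean log2 CPM of at least 2 and no overlap between libraries, and up to 4 members per list with the smallest adjusted p. Names of the form Gm or Rik and identifiers without a symbol were left out. The text names a part of these. One named result is not reported here.

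Transcripts entered a smartSHAPE comparison with at least 100 nucleotides scored in all profiles compared. For each, Pearson r along the nucleotides and the difference of mean reactivity were computed in Python 3.11.15 with numpy 2.4.6 and SciPy 1.17.1, and a shift of 25 scored nucleotides served as control. No table used here joins the transcript identifiers to genes, so transcripts are named by identifier. Gene positions came from RefSeq gene spans of GRCm38.p6, the assembly of mm10, matched by symbol. They were found for 12581 of the 14225 tested genes (88.4%).

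Each step was tested on simulated data. For RNA-seq the spread of each gene was taken from the fit of all 12 libraries and was the same in every group. For KO against WT at 3 h, with 13860 simulated genes, edgeR called 0%, 28.0%, 80.0% and 94.0% of genes changed 1.5, 2, 4 and 8-fold, and 4 of 13620 unchanged genes. For 0 h, with 13791 genes, it called 6.00%, 18.0%, 84.0% and 96.0%. For LPS in WT, with 13788 genes, these were 0%, 18.0%, 86.0% and 86.0%, for LPS in KO, with 13841 genes, 0%, 34.0%, 94.0% and 96.0%, and for the interaction, with 13852 genes, 0%, 6.00%, 66.0% and 94.0%. camera called the changed list and 0 of 20 unchanged lists at 3 h. The simulated genes varied independently of each other, so this does not check camera on lists of correlated genes. Simulated transcripts with a true r of 0.5 gave a median of 0.501, and 1000 of 1000 simulated peaks were placed in their gene.

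Alternatives were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0, a fit without robust estimation, a replicate block, the 6 libraries of the groups compared, each library left out in turn, other minima of scored nucleotides, Spearman's rho, and a stricter or merged peak list. Fits without WT 0 h libraries 1 and 2, fits of genes in both tables, lists without chromosomes 1, 2 and 17, and the set of genes with a peak in the gene span were added after the data were examined. Comparisons that need UTRs, a genome sequence or a map from transcripts to genes were not run. Figures were drawn with matplotlib 3.10.9.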

Results

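The series held 36 samples in 16 groups and joined a low-input method of RNA structure probing to experiments on the RNase Regnase-1, written Reg1 in the labels and encoded by Zc3h12a. smartSHAPE marks flexible nucleotides of RNA with NAI-N3, a compound that acylates the ribose of unpaired bases, and reads the marks by sequencing. It was applied to 16 samples of HEK293T, a human embryonic kidney cell line, of which 8 were treated with the solvent DMSO. It was also applied to 4 samples of mouse colonic macrophages, sorted by the surface protein Ly6C into a high (Ly6Chi) and a low (Ly6Clo) subset. RNA-seq covered 12 libraries of immortalised bone marrow-derived macrophages (iBMDMs), with 3 libraries each of Reg1 knockout (KO) and wild-type (WT) cells before and 3 h after lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages. The uvCLAP samples (4) mapped the RNA bound by FLAG-tagged Reg1, or by GFP as control, in the mouse macrophage line Raw264.7 after 3 h of LPS.

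The depth of the RNA-seq libraries lay between 7119202 and 15271013 counts. The WT 0 h libraries held 12869856, 7712985 and 7119202 counts and the KO 0 h libraries 12487523, 11253301 and 11867074. At 3 h the WT libraries held 10910316, 8139819 and 7443242 and the KO libraries 11951521, 15271013 and 11627392. The smartSHAPE files gave reactivity scores without read depths, so the depth behind each score is unknown. Each smartSHAPE group was deposited as 1 profile for its pair of samples, so these values have no replicate error and no test.

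The HEK293T series asked how much RNA the probing needs. Transcripts with at least 100 scored nucleotides numbered 54332 at 1 ng of RNA, 63087 at 5 ng, 59986 at 25 ng and 59702 at the highest input. The scored nucleotides summed to 42690553, 52679321, 49292978 and 47986769, and 53575 transcripts passed the minimum at all 4 inputs. The mean reactivity was 0.325 at 1 ng, 0.332 at 5 ng, 0.335 at 25 ng and 0.320 at the highest input, on the authors' scale from 0 (unreactive) to 1.

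Reactivity patterns within transcripts were compared with the profile of the highest input. Over the 52561 transcripts scored at 100 or more common nucleotides, the median Pearson r along a transcript was 0.721 for 1 ng, 0.753 for 5 ng and 0.737 for 25 ng. The same transcripts gave 0.763 between 5 and 25 ng, and a profile shifted by 25 scored nucleotides against the highest input gave -0.01 at both 1 and 5 ng. The most abundant transcripts, ranked by the deposited score that was read as abundance, had a median r of 0.755 at 1 ng, against 0.697 for the least abundant. Scores differed by 0.5 or more at 3.44% of the nucleotides between 1 ng and the highest input, and at 2.69% between 5 ng and the highest input. These correlations run over nucleotides, which are not independent replicates.

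**Figure D1:**
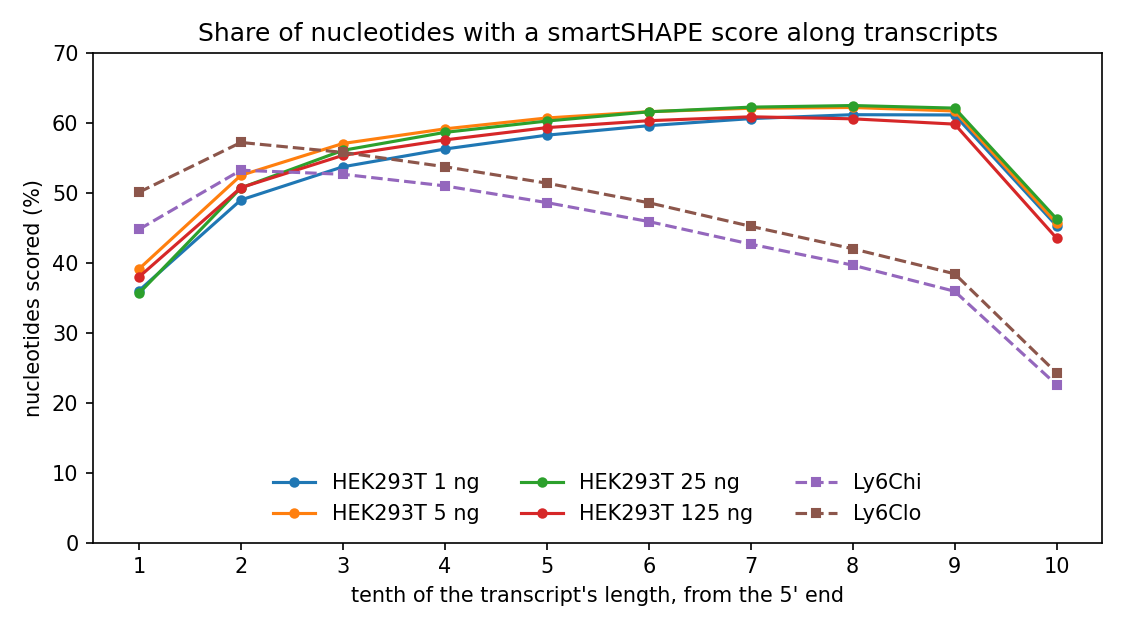
Share of nucleotides with a smartSHAPE score (percent, vertical axis) in each decile of transcript length from the 5′ end (horizontal axis), with 1 deposited profile per line and no error bars. Only transcripts with at least 300 scored nucleotides in the profile entered. Over all listed transcripts the share was 40.4% at 1 ng, 30.3% in Ly6Chi and 33.3% in Ly6Clo. In the HEK293T profiles the share was highest in the 7th or 8th decile (61.2% at 1 ng in the 8th), while in Ly6Chi and Ly6Clo macrophages it peaked in the 2nd decile (53.2% and 57.2%) and ended at 22.6% and 24.3%.

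The colonic macrophage profiles asked how RNA structure compares between the Ly6Chi and Ly6Clo subsets. Ly6Chi cells had 17855 transcripts with at least 100 scored nucleotides and Ly6Clo cells 23859. Of these, 17579 were covered in both, 276 in Ly6Chi alone and 6280 in Ly6Clo alone. Over 17390 transcripts the median Pearson r between the subsets was 0.690. Transcripts had a lower mean reactivity in Ly6Chi, with a median difference of -0.0200 (medians of 0.30 in Ly6Chi and 0.321 in Ly6Clo), and 14.7% of them were higher in Ly6Chi.

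Single macrophage transcripts spanned a wide range of agreement. Among 10781 transcripts with at least 300 common nucleotides, 859 had an r over 0.9 and none an r under 0.3. The transcript ENSMUST00000205377.1 had the largest excess in Ly6Chi, with means of 0.366 and 0.317 over 343 nucleotides, followed by ENSMUST00000135367.1 with 0.315 and 0.276 over 303. The largest excess in Ly6Clo belonged to ENSMUST00000107887.7, with means of 0.266 in Ly6Chi and 0.365 in Ly6Clo over 324 nucleotides. For ENSMUST00000175964.1 the means were 0.282 and 0.380 over 348 nucleotides. The Ly6Chi profile held more scores of exactly 0 (median of 24.3% per transcript) than the Ly6Clo profile (14.8%), and the files do not pair these transcript identifiers with gene names.

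The libraries of KO cells and of WT cells at 3 h were alike within their groups, with correlations of log2 CPM from 0.987 to 0.997. The WT 0 h libraries stood apart from each other: library 2 had a correlation of 0.794 with library 1 and 0.613 with library 3. Gapdh, the glycolytic housekeeping gene, had 107 CPM in WT 0 h library 2 against 1820 and 2618 in libraries 1 and 3. The RNA component of RNase MRP, Rmrp, had 17.7 CPM there against 2587 and 4274. No pair of libraries agreed within sampling noise, so all 12 were counted as separate samples.

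Zc3h12a, the targeted gene (ENSMUSG00000042677.7, chromosome 4, 125118414 to 125127881, mm10), had 15, 2.60 and 22.9 CPM in the WT 0 h libraries and 19.9, 17.5 and 19.4 in the KO 0 h libraries. At 3 h it had 89.2, 85.7 and 87.7 CPM in WT and 62.1, 60.1 and 66.0 in KO. The difference at 3 h was -0.48 ± 0.49 on the log2 scale (SE, n = 3 and 3) with an adjusted p of 0.628 in edgeR's quasi-likelihood test. Without WT 0 h library 2 the edgeR adjusted p was 0.00625. With only the 6 libraries at 3 h it was 1.54e-06. The labels do not say which part of the gene was altered, so its transcript level does not check the KO labels.

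The comparison of KO with WT cells after 3 h of LPS asked which mRNAs differ in cells without Regnase-1, an RNase known to degrade inflammatory mRNAs through stem-loops. The labels do not say whether the KO and WT cells are clones or separate lines, so no difference between them is assigned here to the loss of Regnase-1 alone. mRNAs on the fixed list of Regnase-1 targets were higher in KO. Interleukin 6 (Il6, chromosome 5, 30013114 to 30019975, mm10) rose from 13.2 ± 0.288 to 49.4 ± 2.15 CPM (SD, n = 3), a log2 difference of 1.91 ± 0.19 (SE) with an edgeR adjusted p of 1.54e-04. Il1b, which encodes interleukin 1 beta, rose from 94.7 ± 3.92 to 547 ± 11.2 CPM (5.77-fold), and Ptgs2, the inducible cyclooxygenase, from 271 ± 10.7 to 969 ± 5.95 (3.57-fold). Of 22 measured targets, 12 rose and 0 fell (14 and 1 when adjusted over the list alone), with a median log2 difference of 1.2. The list passed limma's camera test with an adjusted p of 4.17e-09, and with an adjusted p of 0.00292 with an estimated correlation. In fry its p was 3.23e-07.

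Inflammatory cytokines and chemokines and interferon-stimulated genes rose with them in KO cells at 3 h, on lists that can share members. Of 31 measured cytokine and chemokine genes, 20 rose and 0 fell (23 and 0 when adjusted over the list alone). Among them the chemokine gene Cxcl16 rose 15-fold, from 7.16 ± 0.550 to 107 ± 0.997 CPM, and Il1rn, the interleukin 1 receptor antagonist, 4.32-fold. Of 53 interferon-stimulated genes, 40 rose and 0 fell (45 and 1 when adjusted over the list alone). The antiviral GTPase Mx1 went from 1.90 ± 0.441 to 77.9 ± 2.91 CPM, Ddx60 from 1.36 ± 0.325 to 41.8 ± 0.356 and Cmpk2 from 121 ± 7.54 to 859 ± 19.6. Usp18, which removes the ubiquitin-like protein ISG15, rose 5.31-fold, Rtp4 3.64-fold and Ifi44 30.3-fold. In limma's camera test the adjusted p was 3.72e-15 for cytokines and 9.22e-34 for interferon-stimulated genes. With an estimated correlation these were 0.00233 and 3.06e-04.

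**Figure D2:**
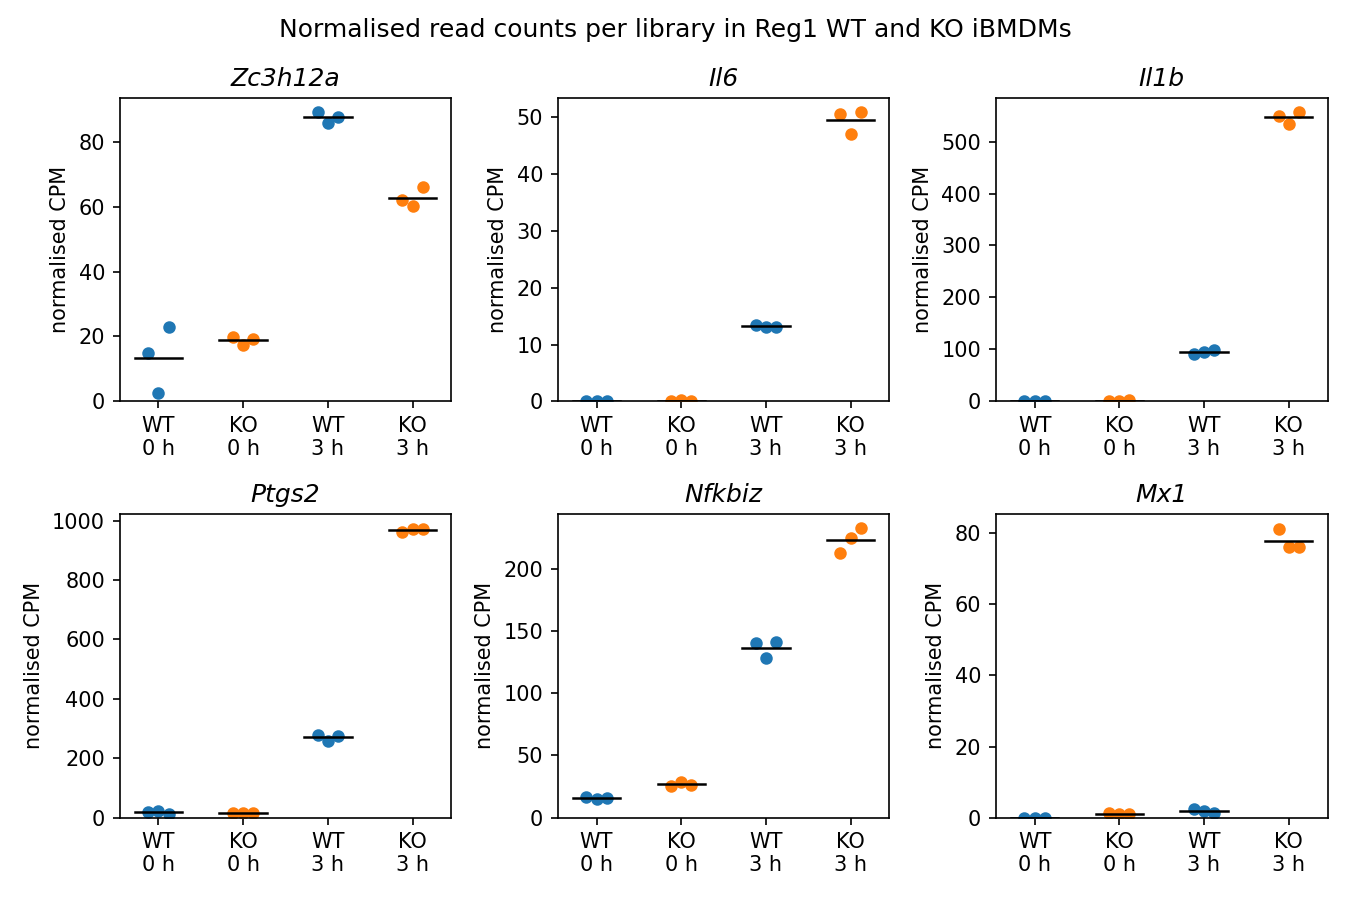
Normalised read counts (CPM, vertical axes from 0) of Zc3h12a, Il6, Il1b, Ptgs2, Nfkbiz and Mx1 in the 12 iBMDM libraries, with 1 point per library and a line at the mean of 3. The KO 3 h points lie above the WT 3 h points for Il6 (49.4 against 13.2 CPM), Il1b, Ptgs2, Nfkbiz and Mx1, and below them for Zc3h12a (62.7 against 87.5), while WT 0 h library 2 lies lowest of its group for Zc3h12a (2.60).

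Smaller shares of other immune lists rose in KO at 3 h. Of 31 NF-kappaB components and feedback genes, 8 rose (9 when adjusted over the list alone), among them Tnip3 (8.45-fold), Nfkbiz (1.64-fold), Birc3 (1.76-fold) and Traf1 (2.0-fold). The camera adjusted p of this list was 5.04e-04, with an adjusted p of 0.208 with an estimated correlation. Of 24 genes of MHC class II and antigen presentation, 10 rose (13 when adjusted over the list alone), with a camera adjusted p of 1.41e-07 and an adjusted p of 0.134 with an estimated correlation. H2-Ab1, an MHC class II chain, had 3 counts in WT and a ratio of 118 (95% counting interval 40.2 to 574), and H2-Aa rose 46.7-fold. Both lie on chromosome 17, and 16 of the 24 members lie on chromosomes 1, 2 and 17, where the levels of many genes differed together, but the list kept its camera call without the genes of these chromosomes. Of 30 genes of glycolysis and the hypoxia response, 8 rose (9 when adjusted over the list alone), such as Ndrg1 (7.04-fold), Bnip3 (3.88-fold), the prolyl hydroxylase Egln3 (2.91-fold) and Pfkfb3 (2.02-fold). Their camera adjusted p was 1.34e-04, with an adjusted p of 0.208 with an estimated correlation.

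A few genes of cholesterol handling were lower in KO at 3 h. Of 11 genes of cholesterol efflux and LXR targets, 3 fell (3 when adjusted over the list alone), with the cholesterol transporter Abca1 1.88-fold lower (-0.91 ± 0.10 on the log2 scale) and the desaturase Scd2 going from 412 ± 10.2 to 243 ± 17.3 CPM. For this list the camera adjusted p was 0.00235, with an adjusted p of 0.208 with an estimated correlation. Of 24 cholesterol biosynthesis genes, 2 fell (2 when adjusted over the list alone), among them Acat2 with a log2 difference of -1.10 ± 0.11. The camera adjusted p was 0.0301, with an adjusted p of 0.119 with an estimated correlation. Acat2 lies on chromosome 17, and the camera call of this list was lost without chromosomes 1, 2 and 17 and also without WT 3 h library 1. Zfp36l2, an mRNA-destabilising protein gene of chromosome 17, fell by 1.07 on the log2 scale.

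Large differences at 3 h were also found in genes outside these lists. The long noncoding RNA Xist, which silences the X chromosome in female cells, had 1849 ± 173 CPM in WT and 3 counts in all KO libraries, a ratio of 22058 (95% counting interval 7547 to 106963). The Y-linked genes Kdm5d and Uty had at most 1 count in any of the 12 libraries, and Ddx3y and Eif2s3y had 0 counts, in WT and KO alike. Nedd4, a ubiquitin ligase gene, went from 582 ± 10.6 to 2.98 ± 0.655 CPM. The log2 difference was -5.19 for Col23a1, -4.59 for Hp, -4.51 for Mcf2l, -4.34 for Spink5, -3.96 for Slpi and -3.67 for Ogdhl. The cyclin gene Ccnd2 went from 0.128 ± 0.221 to 13.7 ± 1.54 CPM, and Ly6a from 0.291 ± 0.102 to 13.6 ± 0.884. Ccdc114 had 2 counts in WT, with a ratio of 112 (30.7 to 928).

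Other fixed lists did not pass limma's camera test at 3 h with all libraries and genes. Some were called in other fits: mRNA decay and RNA-binding regulators without WT 0 h library 2, without library 3 and without libraries 1 and 2, NRF2 targets without WT 0 h library 2, and resident colonic macrophage markers without chromosomes 1, 2 and 17. The camera adjusted p was 0.0742 for mRNA decay and RNA-binding regulators, 0.135 for the cell cycle, 0.135 for NRF2 targets, 0.283 for mitochondrially encoded mRNAs and 0.340 for alternative activation. It was 0.340 for macrophage identity, 0.645 for the unfolded protein response, 0.715 for lysosomal genes, 0.140 for monocyte-like and 0.310 for resident colonic macrophage markers. Iron handling genes (0.919) had a median of -0.08 and a mean of 0.02, and ribosomal protein genes (0.837) a median of -0.02 in a test that pointed up. Markers of other cells were too few for a test, with 2 measured for fibroblasts, 1 for epithelial cells, 2 for T and NK cells, 1 for B and plasma cells, 3 for neutrophils, 4 for dendritic cells and 0 for mast cells and eosinophils. The best expressed marker in each averaged 1.77 (Acta2), 0.907 (Lgals4), 84.6 (Il7r), 86.2 (Xbp1), 30.0 (Mmp8) and 94.9 (Tcf4) CPM. At 3 h, 2 fibroblast, 1 T and NK cell, 3 neutrophil and 1 dendritic cell markers differed between KO and WT in edgeR's test. No epithelial or B and plasma cell marker did. Over all genes tested, 1436 of 14225 differed.

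In all, 1436 of 14225 genes differed between KO and WT at 3 h in edgeR's quasi-likelihood test, with 927 higher and 509 lower in KO. The balance of higher and lower genes was not kept: they numbered 2255 and 2806 without WT 0 h library 2, 3611 and 3444 with the 6 libraries at 3 h alone, and 3556 and 4000 without WT 0 h libraries 1 and 2, a fit chosen after the data were seen. The count was 858, 771 and 793 without WT 3 h library 1, 2 or 3, and 764, 759 and 798 without KO 3 h library 1, 2 or 3. It was 5061 without WT 0 h library 2, 2916 without WT 0 h library 3 and 7055 with the 6 libraries at 3 h alone, so it depended on which libraries entered the fit.

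Before LPS, interferon-stimulated genes already stood higher in KO cells. Of 53, 37 rose and 0 fell (40 and 1 when adjusted over the list alone), with a median log2 difference of 2.04. Rtp4 went from 0.588 ± 0.0686 to 12.4 ± 1.31 CPM (SD, n = 3), Cmpk2 from 1.44 ± 0.429 to 20.5 ± 1.25 and Oasl2 from 4.24 ± 0.563 to 27.7 ± 2.06. Mx1 had 0 counts in WT and was at least 10.9-fold higher in KO (floor of 3 counts over the group), and Ddx60 had 1 count, a ratio of 114 (95% counting interval 20.2 to 4548). Of 31 cytokine and chemokine genes, 11 rose (14 when adjusted over the list alone), among them Cxcl16 (11.1-fold), Ccl5 (6.04-fold) and Cxcl10 (6.04-fold). In limma's camera test the adjusted p was 4.28e-27 for interferon-stimulated genes and 8.86e-06 for cytokines. With an estimated correlation these were 6.94e-04 and 0.0408.

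The Regnase-1 target list was not called before LPS. Of its 22 measured members, 5 rose and 1 fell (5 and 1 when adjusted over the list alone), Egln3 among those that rose (3.04-fold), and the camera adjusted p was 0.0692. It was called with no filter on low counts and without KO 0 h library 1. Of 30 genes of glycolysis and the hypoxia response, 13 rose (14 when adjusted over the list alone), with Adm 4.47-fold higher. Their camera adjusted p was 2.46e-07, with an adjusted p of 0.168 with an estimated correlation. Of 24 MHC class II and antigen presentation genes, 9 rose (11 when adjusted over the list alone), with the class II transactivator Ciita going from 0.510 ± 0.597 to 18.3 ± 2.01 CPM. H2-Aa had 1 count in WT, a ratio of 201 (35.8 to 7982). The camera adjusted p was 1.92e-06, with an adjusted p of 0.177 with an estimated correlation, and the call was lost without chromosomes 1, 2 and 17.

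Cholesterol biosynthesis genes were lower in KO before LPS. Of 24, 5 fell (10 when adjusted over the list alone), including Acat2 (-1.18 ± 0.11 on the log2 scale) and Fdps (-0.95 ± 0.18). In limma's camera test their adjusted p was 3.21e-04 and 0.0237 with an estimated correlation. With the 6 libraries at 0 h alone, the edgeR adjusted p of Fdps was 0.108. Abca1 fell by 0.79 on the log2 scale, with an edgeR adjusted p of 8.63e-04 and of 0.0743 with those 6 libraries. Mitochondrially encoded mRNAs included 1 higher and 2 lower of 10 (1 and 7 when adjusted over the list alone), and lysosomal genes 2 higher and 1 lower of 37 (0 and 1 when adjusted over the list alone). The camera adjusted p was 0.00863 and 0.0338 for these lists, with an adjusted p of 0.522 with an estimated correlation for both. The camera call of the mitochondrial list was lost without WT 0 h library 1 and without library 2, and that of the lysosomal list without library 2, so neither is a firm difference.

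At 0 h Xist had 3564 ± 1595 CPM in WT and 0.185 ± 0.0552 in KO, and Nedd4 832 ± 193 and 3.90 ± 0.501. The log2 difference was -5.29 for Spink5 and -4.15 for Col23a1. Sgsm1 had 3 counts in WT and a ratio of 142 (48.3 to 691), and Ccdc114 1 count and a ratio of 365 (65.2 to 14449). Zc3h12a differed by 0.49 ± 0.50 with an edgeR adjusted p of 0.564. In all, 1740 genes differed at 0 h in edgeR's quasi-likelihood test, with 953 higher and 787 lower in KO (2229 and 2999 without WT 0 h library 3). The count was 1052, 3912 and 5228 without WT 0 h library 1, 2 or 3, 848, 844 and 878 without KO 0 h library 1, 2 or 3, and 251 with the 6 libraries at 0 h alone.

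The differences at 0 h and 3 h overlapped. They share no library, but both come from 1 fit with a shared spread per gene, so part of the overlap beyond independent lists may follow from the fit. Higher in KO at both times were 490 genes, where independent lists of these sizes would share 62.1, and lower at both were 182, where they would share 28.2. There were 2 genes higher at 3 h and lower at 0 h (51.3 for independent lists) and 0 the other way (34.1). The Pearson r of the log2 differences was 0.583 over 14225 genes and the Spearman rho 0.294, across genes, which are not independent replicates.

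Genes of some chromosomes differed together between KO and WT. At 3 h the 432 genes of chromosome 17 with a mean log2 CPM above 3 had a median log2 difference of -0.49, with 85.9% lower in KO against 52.6% of the genes elsewhere. The lowest median of 10000 random lists of that size was -0.13. The 197 genes of chromosome 2 from 150 Mb to its end had a median of -0.50 and the 284 genes of chromosome 1 up to 120 Mb a median of 0.44, against -0.03 for 6975 genes of the other autosomes. In the KO 0 h libraries against WT 0 h library 3 these medians were -0.40, -0.47 and 0.52. Against library 1 they were -0.20, -0.35 and 0.33, and against library 2 chromosome 17 was higher in KO, with a median of 0.92, so the blocks at 0 h depended on the WT library.

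**Figure D3:**
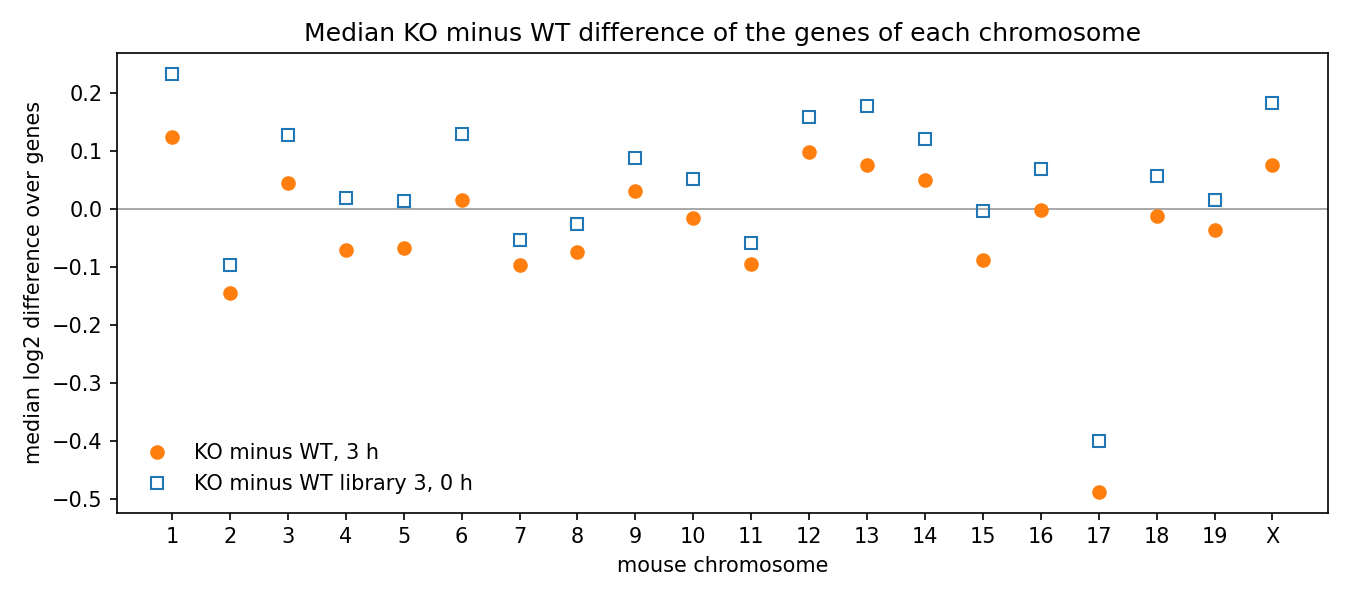
Median log2 difference between KO and WT over the genes of each chromosome (vertical axis, log2 scale, with a line at 0) by mouse chromosome (horizontal axis), for the 3 h libraries (filled) and for the KO 0 h libraries against WT 0 h library 3 (open). Chromosome 17 lies lowest in both sets, at -0.49 and -0.40.

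The comparison of 3 h with 0 h of LPS gave the response of the cells themselves. In WT cells inducible cytokine genes rose from near absence. Il1b went from 0.361 ± 0.230 to 94.7 ± 3.92 CPM (SD, n = 3), the chemokine genes Cxcl10 from 3.09 ± 1.33 to 882 ± 13.7 and Ccl5 from 1.95 ± 0.667 to 392 ± 22.9, and Nos2, the inducible nitric oxide synthase, from 0.214 ± 0.0600 to 74.4 ± 13.1. Il6 had 2 counts at 0 h and a ratio of 198 (95% counting interval 54.3 to 1640), Csf3 had 1 count and a ratio of 258 (45.9 to 10246), and Gbp5 had 2 counts and a ratio of 579 (160 to 4784). Mx1 had 0 counts at 0 h and was at least 19-fold higher at 3 h. Among the falls, the log2 change was -5.27 for Gpr183, a chemotactic receptor gene, -5.00 for Tlr8, -4.13 for Cnr2, -3.15 for Arrdc3 and -3.07 for the chemokine receptor gene Cxcr4.

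The lists of inducible genes moved together in WT cells. Of 31 cytokine and chemokine genes, 26 rose (28 when adjusted over the list alone), and of 53 interferon-stimulated genes 47 rose (48 when adjusted over the list alone), with Gbp2 138-fold and Oasl2 34.6-fold higher. Of 31 NF-kappaB genes 23 rose and 0 fell (23 and 2 when adjusted over the list alone), such as Traf1 (136-fold) and the feedback inhibitors Tnfaip3 (11.7-fold) and Nfkbiz (8.66-fold). Of 22 Regnase-1 targets 16 rose and 2 fell (17 and 2 when adjusted over the list alone). In limma's camera test the adjusted p with an estimated correlation was 4.08e-04, 2.18e-04, 0.0256 and 0.00154 for these 4 lists. The iron-binding protein gene Lcn2 went from 0.420 ± 0.333 to 27.2 ± 5.31 CPM.

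A further 8 lists passed limma's camera test in WT cells and lost the call with an estimated correlation. Of MHC class II and antigen presentation genes 12 rose (13 when adjusted over the list alone), of alternative activation genes 4 rose and 1 fell (4 and 1 when adjusted over the list alone), and of NRF2 targets 8 rose and 1 fell (8 and 1 when adjusted over the list alone). These lists had camera adjusted p values of 1.26e-04, 0.0265 and 6.45e-04, with an adjusted p of 0.202, 0.191 and 0.191 with an estimated correlation. Unfolded protein response genes (8 up and 2 down) and monocyte-like markers (5 up and 1 down) numbered 10 and 3, and 7 and 2, when adjusted over the list alone, with an adjusted p of 0.296 and 0.191 with an estimated correlation. Lysosomal genes went both ways (4 up and 5 down, or 4 and 3 when adjusted over the list alone), with an adjusted p of 0.442 with an estimated correlation. Of 10 mitochondrially encoded mRNAs 8 fell (9 when adjusted over the list alone), and of 49 ribosomal protein genes 3 rose (0 when adjusted over the list alone), with an adjusted p of 0.322 and 0.351 with an estimated correlation. Camera calls were also lost without WT 0 h library 2 or 3 (alternative activation), without WT 3 h library 1 (lysosome) and with no filter on low counts (monocyte-like). Without WT 0 h libraries 1 and 2 the alternative activation, lysosomal, unfolded protein response and mitochondrial lists lost it, and without chromosomes 1, 2 and 17 the MHC class II, lysosomal and monocyte-like lists.

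Zc3h12a itself rose with LPS. In WT cells the log2 change was 2.69 ± 0.53 with an edgeR adjusted p of 0.00504, and of 0.0985 with the 6 WT libraries alone. In KO cells it was 1.73 ± 0.50 with an edgeR adjusted p of 0.0338. That call was lost without WT 0 h library 1, without any 1 of the KO libraries and without WT 3 h library 2 or 3, with edgeR adjusted p values up to 0.114, and with no filter on low counts (0.0574).

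In all, 4232 genes changed with LPS in WT cells in edgeR's test (1505 up, 2727 down) and 2931 in KO cells (1375 up, 1556 down). The balance of rises and falls, though not the sign of the shared calls, depended on the WT 0 h libraries: in WT cells 2931 rose and 2773 fell without library 2, and 2539 and 1630 without libraries 1 and 2, with the same sign in 3891 of 3891 and 2245 of 2246 genes shared with the 4232. In KO cells the balance turned with DESeq2 size factors in edgeR (1478 up, 1346 down) and with DESeq2 (1776 and 1651). It kept more falls without WT 0 h library 2 (3099 and 3380). Among the genes that rose in KO cells, Il12b, which encodes a chain of interleukin 12, had 0 counts at 0 h and was at least 255-fold higher at 3 h. Il1b, Nos2, Il6 and Cxcl2 rose 375, 372, 347 and 309-fold. The log2 change was -5.48 for Gpr183, -4.22 for Lpin1, -3.97 for Cxcr4 and -3.86 for Irf2bp2. The WT count was 2450 and 8093 without WT 0 h library 1 or 3, 2756, 2056 and 2253 without WT 3 h library 1, 2 or 3, and 485 with the 6 WT libraries. The KO count was 6479 and 4692 without WT 0 h library 2 or 3, 1927 without KO 0 h library 2, 1910 and 1864 without KO 3 h library 2 or 3, and 9208 with the 6 KO libraries.

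The interaction of genotype and LPS asked whether the KO difference itself changed between 0 and 3 h. It passed edgeR's test in 43 genes (1880 at an unadjusted p under 0.05), with 25 above and 18 below 0. With DESeq2 size factors in edgeR it was 42, split 29 and 13, but without WT 0 h library 2 most genes lay below 0 (256 above, 390 below), as they did without libraries 1 and 2 (552 and 1167). Ptgs2 had 17.9 ± 4.54 and 15.8 ± 0.136 CPM in WT and KO at 0 h and 271 ± 10.7 and 969 ± 5.95 at 3 h, an interaction of 2.02 ± 0.23 on the log2 scale with an edgeR adjusted p of 0.0117. Rtp4 had an interaction of -2.49 ± 0.21, since its 20.4-fold excess in KO at 0 h was 3.64-fold at 3 h. For Zc3h12a it was -0.97 ± 0.70 with an edgeR adjusted p of 0.508. The count of 43 was 12, 646 and 3491 without WT 0 h library 1, 2 or 3, 2 without WT 3 h library 1 and 1 without any 1 of the 8 other libraries.

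The uvCLAP peaks asked where Reg1 binds RNA. The deposited list held 15566 peaks on mm10, 6867 on the plus and 8699 on the minus strand, of which 14552 were 50 bases wide. The authors' reads per peak had a median of 40 and ranged from 24 to 58727. A gene span of the RefSeq annotation of this build held 83.4% of the peaks, with 77.1% in a protein-coding gene and 16.6% outside genes, and 5523 protein-coding genes had a peak. Read along the strand of the peak, 14.6% of the peaks in a single protein-coding gene lay in the last decile of its span and 8.35% in the first. The annotation held gene spans without exons or UTRs, so a finer position is not given here, and the strand of the gene was not compared.

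Peaks overlapped the spans of 12 of the 26 genes of the Regnase-1 target list, introns included, with 57 peaks in all on either strand. Of the tested protein-coding genes, 4565 had a peak in their span and 6083 had none. The 2 shares are not like for like, since the list counts all 26 written genes, of which 22 were measured. Gene span was not matched either, with a median of 37876 bases for tested genes with a peak and 16330 for the others. This count therefore does not decide whether the list stood out. Tnf, which encodes tumour necrosis factor, had 13, the strongest at chromosome 17, 35199401 to 35199500, with 5532 reads. Il1a had 9, Ptgs2 8 (7 on the plus and 1 on the minus strand), the early response gene Ier3 7, Cxcl2 6 and Il1b 5, of which the strongest lay in the last decile of the Il1b span at chromosome 2, 129365201 to 129365250, with 4286 reads. Of the 10 peaks with the best p and reads, 9 overlapped a small nucleolar RNA, a class that guides chemical modification of other RNAs. The first lay at chromosome 9, 15313801 to 15313950, within Taf1d, with 58727 reads. The list does not separate Reg1 from GFP libraries, so no background can be set beside these peaks.

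Genes with a peak in their span were shifted towards higher levels in KO at 3 h. The 4565 tested genes with a peak had a median log2 difference of 0.06 and the 6083 others -0.11, a gap of 0.169 with a p of 0.0106 in limma's camera test. The camera p was 0.0656 with an estimated correlation. Against other genes matched on mean log2 CPM and on gene span the gap was 0.0914, with a camera p of 0.0726. This set was chosen after the data were examined, in place of a planned set of genes with a peak in the 3′ UTR.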

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

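Among the tests below, the regroupings of libraries and the tests of depth, gene span and other cells were set before their results were seen, and the fits without WT 0 h libraries 1 and 2 were chosen afterwards. The difference between KO and WT was itself different at 3 h and at 0 h of LPS, by the interaction term of edgeR's quasi-likelihood test, in 43 genes. Genes whose KO difference moved upwards with LPS included Setdb2 (2.29 on the log2 scale), the RNA sensor Tlr3 (2.28), Ptgs2 (2.02), Il1rn (1.68), Evi2a (1.64), Rin2 (1.56), the interferon-inducible GTPase gene Igtp (1.53) and Ms4a6c (1.33). It moved downwards in Arhgap23 (-2.59), Rtp4 (-2.49), Ifit3 (-2.14), Isg15 (-1.99), Ccl5 (-1.75), Irf2bp2 (-1.71), Klf10 (-1.57) and Oasl2 (-1.55). For Rtp4, Ifit3, Isg15, Ccl5 and Oasl2 the KO cells were higher at both times, with a smaller ratio at 3 h. Of the 16 genes named here, 15 lost the call when 1 of several libraries was left out, with Rtp4 the exception.

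By the same term, 5 of the fixed lists passed limma's camera test, although few of their members passed alone and no list kept the call with an estimated correlation. Of 22 Regnase-1 targets 1 was above and 0 below 0 (2 and 0 when adjusted over the list alone), and the test pointed up with a camera adjusted p of 6.66e-04 (adjusted p = 0.0983 with an estimated correlation). Of 31 cytokines and chemokines 1 was above and 1 below (2 and 3 when adjusted over the list alone), pointing up with a camera adjusted p of 0.00140 (0.211 with an estimated correlation). None of 10 mitochondrially encoded mRNAs passed (4 and 0 when adjusted over the list alone), in a test pointing up with a camera adjusted p of 0.00110 (adjusted p = 0.60 with an estimated correlation). None of 11 cholesterol efflux and LXR targets passed (0 and 1 when adjusted over the list alone), nor any of 37 lysosomal genes (0 and 0 when adjusted over the list alone). Both tests pointed down with a camera adjusted p of 0.0395 (0.60 and 0.631 with an estimated correlation).

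Chance was set against the 43 interaction genes by regrouping libraries by genotype within each time. Of 100 groupings, the real one included, 2 gave as many genes. This does not decide about chance, because regrouping mixes KO and WT libraries, which differ at both times, and only 5 of the 99 others called any gene. The highest other grouping gave 423 genes, many times the real count, which points to a structure of the samples. That grouping exchanged all labels at 3 h and, at 0 h, WT library 2 with KO library 2. Exchanging all labels at 3 h keeps both groups whole and puts the genotype difference shared by the 2 times into the interaction. The count without WT 0 h library 3 was 3491, without library 2 646 and without library 1 12.

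The spread of the WT 0 h libraries underlies the doubt about these genes, and the labels put all 3 in the same group. Depth does not account for it, because at equal depth the lowest correlation among the 3 was 0.615, against 0.613 as deposited. A trend on gene span, introns included, is not the whole of it, because with that trend removed the value was 0.652 (0.638 before). Transcript length was not tested, and library 2 had 17.7 and 28.2 CPM of the short RNAs Rmrp and Rpph1 (2587 and 3771 in library 1) but 4955 and 11531 of the long RNAs Xist and Malat1 (3915 and 9538), so a loss by RNA length stays open. For RNA of another cell type in library 2, the prediction was that macrophage identity genes fall about as much as Gapdh, Eef2 and Rplp0. Against library 3 the identity genes had a median of -0.73 on the log2 scale (quartiles -2.01 and 0.31 over 31 genes). Gapdh, Eef2 and Rplp0 had a median of -4.61, so the prediction was not met. These housekeeping genes do not measure how far other RNA would lower identity genes, so an admixture stays undecided. GC content could not be tested without transcript sequences, so a difference in library preparation or RNA quality stays open too.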

How the results depend on the processing

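The fits without WT 0 h libraries 1 and 2, of genes in both tables and without chromosomes 1, 2 and 17, and the settings of the peak-gene set, were chosen after the data were seen. For the genes changed at 3 h, at 0 h, with LPS in WT, with LPS in KO and by interaction, DESeq2 size factors, robust=FALSE and genes in both tables kept each count within 1.5 times. Without WT 0 h libraries 1 and 2 the counts were 7556, 6543, 4169, 8829 and 1719, with a lone WT 0 h library assumed to vary like the other groups. With the 6 libraries compared they were 7055, 251, 485 and 9208. There fewer libraries gave the spread, the WT 0 h libraries entered it or not and the filter kept other genes. These were not tested apart. The counts rose where no WT 0 h library entered and fell where they did, which the number of libraries, 6 in each fit, cannot give alone. DESeq2 called 356 interaction genes, for which the cause was not tested, and the unfiltered table, with more genes tested, 22. Leaving out 1 library gave 759 to 5061 genes at 3 h, 844 to 5228 at 0 h, 2056 to 8093 with LPS in WT, 1864 to 6479 with LPS in KO and 1 to 3491 by interaction.

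Lists called fell from 8 to 3 at 3 h, from 7 to 3 at 0 h and from 12 to 4 with LPS in WT with an estimated correlation, and numbered 12 at 0 h in the unfiltered table, where the cause was not tested. Leaving out 1 library gave 7 to 10, 6 to 9 and 11 to 12 lists. The shift of genes with a peak was 0.1687 with an estimated correlation and 0.0914 when matched on level and span, both no longer past the threshold, and 0.1620 to 0.1682 with 1 library left out.

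The replicate numbers did not pair the libraries. Deviations of same-numbered libraries had correlations of 0.18, 0.06 and 0.06 at 3 h, -0.05, -0.05 and 0.09 at 0 h, -0.08, -0.28 and 0.05 between times in WT and -0.01, -0.02 and -0.06 in KO, and 2, 1, 1 and 0 of 3 fitted their own number best. With the replicate block the counts were 503, 625, 1817, 1803 and 1.

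At a minimum of 500 scored nucleotides, HEK293T transcripts numbered 26903, 32226, 30375 and 29508 from the lowest to the highest input, and 30146, 37146, 34905 and 33305 with at least 50% of the length scored, since fewer qualify. The better part of the peaks by p held 7783 by construction. Spearman's rho in place of Pearson's r gave 0.683, 0.719 and 0.703 for 1, 5 and 25 ng and 0.641 for the macrophages, each moved by less than 50% of the interquartile range over transcripts. For 116 results of named genes, 1027 alternatives gave the same direction and call in 981, lost the call in 43, gained it in 3 and turned the direction in 0. These do not count each library left out as an alternative of its own. Most interaction genes named above lost the call when 1 of several libraries was left out.

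Not run were the tests of peaks in 3′ UTRs and of stem-loops and the choice of 1 transcript per gene, which need a UTR annotation, a genome or a transcript map. No paired analysis was possible for smartSHAPE and the peak list because they come from no test. In the self-test, 2-fold changes at 3 h were called in 28.0% of genes, so smaller changes were often not detectable in the fit of all 12 libraries. That fit includes the spread of the WT 0 h libraries. The rate may not hold for the 6 libraries at 3 h alone, where 7055 genes were called.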

Other observations

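Of the tests in this part, the correlation of bins, the medians of chromosomes 7, 15 and 19 and of LPS-unresponsive genes, and the spread between HEK293T profiles were chosen after the results were seen. In KO cells LPS also moved groups of genes outside the inflammatory lists. Of 46 cell cycle genes, 7 fell and 0 rose (7 and 0 when adjusted over the list alone), with the replication licensing factor Cdc6 going from 46.3 ± 1.2 to 13.2 ± 1.00 CPM (SD, n = 3) and the cyclin gene Ccnd1 from 218 ± 3.55 to 51.3 ± 2.66. limma's camera gave this list an adjusted p of 0.00655 and of 0.0252 with an estimated correlation. In WT cells 12 of the 46 fell and 1 rose (12 and 1 when adjusted over the list alone). There the camera adjusted p was 0.113, though more genes fell than in KO cells. In KO cells 7 of 22 NRF2 targets rose and 1 fell (8 and 2 when adjusted over the list alone). Those that rose included the cystine transporter Slc7a11 (8.25-fold), Srxn1 (3.29-fold) and Txnrd1 (2.75-fold). For these the camera adjusted p was 0.00277, with an adjusted p of 0.197 with an estimated correlation. Of 26 genes of the unfolded protein response 7 rose and 2 fell (8 and 2 when adjusted over the list alone), with Atf3 3.32-fold higher. Here the camera adjusted p was 0.0385, with an adjusted p of 0.334 with an estimated correlation.

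Antigen presentation genes rose with LPS in KO cells as well. Of 24, 14 rose (15 when adjusted over the list alone), with the costimulatory receptor gene Cd40 going from 1.87 ± 0.657 to 132 ± 7.30 CPM and the peptide transporter Tap1 from 16.2 ± 0.555 to 132 ± 3.11. The camera adjusted p was 1.44e-07, with an adjusted p of 0.0987 with an estimated correlation. Of 15 monocyte-like markers 4 rose (5 when adjusted over the list alone), among them the lectin receptor gene Clec4e (13.7-fold). Here the camera adjusted p was 0.00913, with an adjusted p of 0.0987 with an estimated correlation.

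The difference between KO and WT at 3 h followed blocks of chromosomes 1, 2 and 17. A bias like that of WT 0 h library 2 is argued against, because chromosomes 7, 15 and 19, which that library shifted about as much as 17, had a median log2 difference of -0.0835 at 3 h over 1324 genes. A different response to LPS stays undecided. At 0 h, before LPS, the blocks of chromosomes 17, 2 and 1 had the same signs against WT libraries 3 and 1. Their medians were -0.40, -0.47 and 0.52 against library 3 and -0.20, -0.35 and 0.33 against library 1. Against library 2 they were 0.92, 0.34 and 0.09, so the 0 h libraries do not settle whether the blocks came before LPS. The 292 genes of chromosome 17 with no called change with LPS had a median of -0.58 (quartiles -0.75 and -0.32). But the self-test, with the spread of all 12 libraries, called 0 of 50 simulated 1.5-fold changes with LPS. A response of that size could thus go uncalled in this fit. A narrower set, with an unadjusted edgeR p above 0.5 for LPS in both genotypes, held 6 genes with a median of -0.49, too few to decide. A difference in copy number between the cell populations stays undecided as well. The medians of 225 bins of 10 Mb at 3 h had a correlation of 0.930 with those of KO against WT 0 h library 3, but of 0.0960 against library 1 and -0.501 against library 2. The loss of Xist and of Nedd4 in KO cells at both times was not tested for a link to it.

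Mean reactivity was lower in Ly6Chi than in Ly6Clo macrophages by a median of 0.020, and the Ly6Chi profile held more scores of 0. Among 2377 transcripts whose shares of zeros differed by at most 2 percentage points the median difference was -0.0037. This does not decide whether the zeros account for it, because a score of 0 is part of the mean, so matching on zeros removes some of the difference by construction. Whether the spread of the method alone would give it stays undecided, since the largest of the 6 median differences between HEK293T profiles of different input was 0.0164 and no replicate profile was used here. Differences in RNA structure between the subsets, which the design names, stay open as untested.

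Splits of 6 libraries into groups of 3 number 10, too few for a share under 0.05, and in each case below 1 of the 10, the real one, gave the real value. For KO against WT at 3 h the real split called 1436 genes and the highest other 0. At 0 h these were 1740 and 0, for LPS in WT 4232 and 1, and for LPS in KO 2931 and 0. The lists called by camera were 8 against 7 at 3 h, 7 against 6 at 0 h and 12 against 11 for LPS in WT, so with the preset correlation other splits called nearly as many lists. For genes with a uvCLAP peak the shift was 0.169 in the real split and 0.0676 in the highest other. Every other split mixes the groups compared, which widens the spread and shrinks the shift by construction. The contrasts of genes and of the shift therefore decide nothing about chance.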
